A study of Mus musculus with 48 samples.

How the data were processed

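Poly(A) RNA of 48 libraries, 24 from hippocampus and 24 from frontal cortex, was prepared with a stranded mRNA kit and sequenced as read pairs of 151 bases, per the labels. STAR, HTSeq and DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without versions or the step each tool served. The deposited value of a gene is a signal: its read count divided by a single factor per library, per the deposited values themselves, since every value is a whole number of reads times 1 factor of its library (100% of values within 0.02 of a whole number). The first 4 entries of a file give unmapped, multimapping, no-feature and ambiguous reads. Files held 15304 genes in hippocampus and 15263 in frontal cortex, 14976 of them in both, after a filter by the authors whose rule is not stated. In them 24 names had been turned into dates by a spreadsheet and 1 name occurred more than once.

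Whole reads were recovered and rescaled jointly within each tissue by TMM (edgeR 4.0.16), because the authors' factors match ones computed separately for vehicle and esomeprazole libraries (in hippocampus the mean ratio to joint factors was 1.07 for vehicle and 0.932 for esomeprazole libraries). Genes passing filterByExpr with a minimum count of 10 were tested, 15062 in hippocampus, 15040 in frontal cortex and 14844 in both together. The test was limma 3.58.1 with a trend on log2 of the normalised reads plus 1, with 1 mean per group, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons were stress within each drug arm and averaged, esomeprazole within each stress arm and averaged, their interaction, and hippocampus against frontal cortex with the differences of both effects. Errors of fold changes are standard errors from limma.

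Before the data were examined, the comparisons, the gene lists, the rule for named genes and a first set of alternatives were fixed. The test fixed then was edgeR quasi-likelihood on counts. Since the deposited values are scaled, limma was used as the main test instead, a choice made after seeing the data. The test fixed then, edgeR with TMM, was run on the recovered reads and stands beside it as an alternative. Of 42 gene lists (22 of cell types, 19 of pathways, 1 of RNA quality), 40 were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, with p adjusted over the lists of a comparison. Mitochondrially encoded genes (0 tested) and erythrocyte genes (3) fell short of the minimum of 5 members. List scores per library were compared by two-sided exact permutation within the other factor (924 regroupings for 6 against 6, 853776 for averaged effects) in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The first principal component was taken over the log2 values of the tested genes in a tissue, and its relation to the no-feature share was tested with 100000 random permutations, or all 5040 for 7 libraries, with p adjusted over 3 relations. Named genes were the 8 largest changes in each direction among called genes with an average log2 CPM of at least 1, and up to 4 members of smallest p of each list that was called or held at least 2 called genes. Where none was called the 3 of smallest p in each direction were taken, and in every comparison Fkbp5, Sgk1, Tsc22d3, Per1, Fos, Nr3c1, Atp4a, Cyp1b1 and Ddah1. Gene positions are from GENCODE vM21 on mm10.

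The alternatives fixed at the outset were median-of-ratios scaling (in limma and in edgeR), no low-count filter, DESeq2 1.42.0, the replicate number as a block, 2 surrogate variables (sva 3.50.0) and an estimated list correlation. Beside them stands edgeR with TMM, the test fixed at the outset. Chosen after seeing the data were a pseudocount of 5 and the deposited scaling. So were, as covariates, the no-feature share, the score of neighbouring-tissue markers (striatum for hippocampus, olfactory bulb for frontal cortex) and both together. Surrogate variables with that score were added then too. So were fits without libraries of a no-feature share under 12% or without those of the rarer marker class. R 4.3.3 was used with the package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.

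Gene reads per library ranged from 25.3 to 42.0 M and all reads from 33.0 to 55.6 M. A 95% Wilson interval on a library's no-feature share is at most 0.013 points to each side; such intervals cover counting error only. In tests on simulated data with 15062 genes, of which 50 were changed per fold size, limma found 28% of 2-fold and 78% of 3-fold changes in a comparison of 6 against 6, and 66% and 96% in an averaged comparison. Of 1.5-fold changes it found 0% and 22%. Of its calls 4 of 96 and 8 of 156 were false. For DESeq2 34 of 160 and 37 of 207 were, and for edgeR 4 of 102 and 7 of 156. Simulated genes varied independently, while the real libraries share a structure (the first principal component below), so these rates need not hold for them. The mouse numbers of both tissues are not stated to mark the same animals, so no pairing was used. Some genes that the rule selected are not reported.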

Results

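RNA was sequenced from the hippocampus and the frontal cortex of male C57BL/6 mice, an inbred laboratory strain, that had been kept in a control or a stress environment and given vehicle or esomeprazole. Esomeprazole is a proton pump inhibitor, a drug that blocks acid secretion in the stomach. Sessions were held on 3 days, the injection into the abdominal cavity followed each session by 60 minutes, and tissue was taken 12 hours after the last injection. The dose is 2 mg/kg in the series description, while the treatment protocol prints 2 g/kg. Each of the 8 groups (4 conditions in each tissue) had 6 libraries, 48 in all. Reads assigned to genes ranged from 25.3 to 42.0 M per library in hippocampus (median 34.5) and from 27.6 to 41.5 M in frontal cortex (median 33.7). In hippocampus the esomeprazole libraries held 3.69 M more gene reads on average than the vehicle libraries (two-sided exact permutation test within stress groups, p = 0.0162).

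The libraries also differed in the share of reads assigned to no feature and in markers of neighbouring tissue. This no-feature share was 5.03% to 20.6% of all reads in hippocampus and 4.50% to 19.9% in frontal cortex. Whether it includes reads inside genes but outside exons is not stated. It was under 12% in 5 hippocampal and 7 frontal cortex libraries. The first principal component held 67.4% of the variance in hippocampus and 71.4% in frontal cortex, and in both tissues every library under 12% lay to one side of all others on it. Its relation to the no-feature share was tested within 3 sets of libraries, chosen after seeing the data. Among the 19 hippocampal libraries from 12% up, Pearson's r was 0.930 and Spearman's rho 0.930 (permutation test, p = 1e-05 and adjusted p = 3e-05 for each), and r was 0.885 without the 2 farthest libraries. Among the 17 of frontal cortex r was 0.923 (permutation p = 0.00189, adjusted p = 0.00283) and rho 0.392 (permutation p = 0.121, adjusted p = 0.182), but the relation rests on 2 libraries, without which r was 0.154. Among the 7 frontal cortex libraries under 12%, r was 0.484 (permutation p = 0.274, adjusted p = 0.274), rho 0.25 (permutation p = 0.595, adjusted p = 0.595), and r without the 2 farthest 0.522. Differences of the no-feature share by stress or drug were within the spread between libraries in both tissues (exact permutation p from 0.487 to 0.873). Markers of striatal neurons, such as the dopamine receptor genes Drd1 and Drd2, were high in 5 hippocampal libraries, 4 of them from stressed esomeprazole mice and 1 from a stressed vehicle mouse. Markers of the olfactory bulb, such as the transcription factor gene Eomes, were low in 7 frontal cortex libraries, 4 of them from non-stressed vehicle mice and 1 from each other group. The score of bulb markers lay from -3.11 to -2.12 in these 7 and from 0.51 to 1.68 in all other frontal cortex libraries. Whether those others held olfactory bulb tissue that the 7 lacked was not tested.

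**Figure D1:**
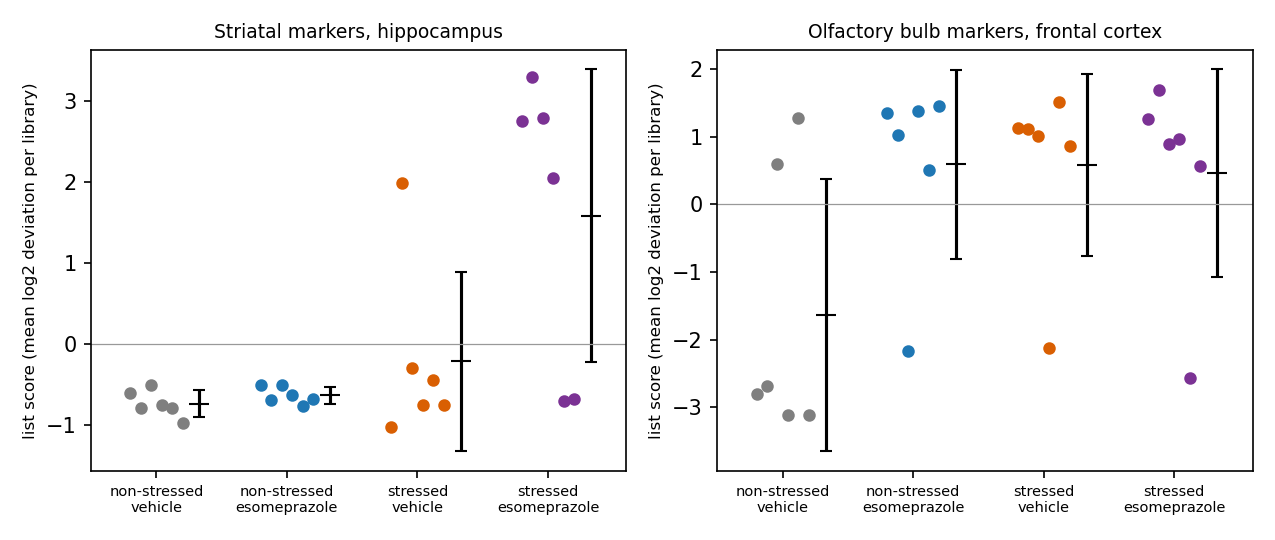
Scores of striatal markers in hippocampal libraries and of olfactory bulb markers in frontal cortex libraries (mean log2 deviation of the list members from their mean over the libraries), with 1 point per library and bars for the mean ± SD of 6 libraries per group. In hippocampus 4 of the 6 libraries of stressed esomeprazole mice lie between 2.06 and 3.31, and the remaining 2 of that group lie at or below -0.68.

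Whether stress changed hippocampal expression was asked first over both drug arms, with 12 stressed against 12 non-stressed mice. Genes that respond to glucocorticoids, the adrenal stress hormones, fell. Of the list, 32 of the 40 members tested were lower after stress, with a median log2 fold change of -0.30 (camera adjusted p = 2.76e-15, and adjusted p = 0.000607 with an estimated correlation). The list score, the mean log2 deviation of the members in a library, differed by -0.35 ± 0.045 (SE), and 12 of 12 stressed libraries lay below the non-stressed mean (two-sided exact permutation test, adjusted p = 0.00028 over 40 lists). Plin4, which encodes a coat protein of lipid droplets (chromosome 17, 56100591 to 56109803, minus strand of mm10), fell by 1.85 ± 0.31 on the log2 scale (SE, limma adjusted p = 0.046). Its normalised read count was 817 ± 467 (SD, n = 6) in non-stressed vehicle mice, 1034 ± 500.3 in non-stressed esomeprazole mice, 211 ± 85.5 in stressed vehicle mice and 255 ± 111 in stressed esomeprazole mice. Lao1, an L-amino acid oxidase gene (chromosome 4, 118961578 to 118968912, plus strand) chosen after its values were seen, fell by 1.58 ± 0.27 (adjusted p = 0.046), with 26.0 ± 14.1 and 29.8 ± 4.96 normalised reads in the vehicle and esomeprazole arms without stress and 11.02 ± 6.08 and 7.38 ± 3.75 with it.

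Within the glucocorticoid list in hippocampus, 11 members were called when adjusted over the list alone, against 1 over all genes, which was Plin4. The kinase gene Map3k6 was at -0.91 ± 0.18 (adjusted p = 0.109), Tsc22d3, the glucocorticoid-induced leucine zipper, at -0.50 ± 0.12 (0.399), Fkbp5, a co-chaperone of the glucocorticoid receptor, at -0.53 ± 0.13 (0.399) and the kinase gene Sgk1 at -0.46 ± 0.11 (0.399). Fkbp5 had 3419 ± 527 and 3414 ± 338 normalised reads without stress (vehicle and esomeprazole, n = 6 each) and 2507 ± 268 and 2345 ± 905 with it. Fos, an immediate early gene of neuronal activity, was at 0.98 ± 0.27 (adjusted p = 0.502), and Lyve1, a hyaluronan receptor gene of perivascular macrophages and lymphatic vessels, at -1.26 ± 0.23 (adjusted p = 0.067).

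**Figure D2:**
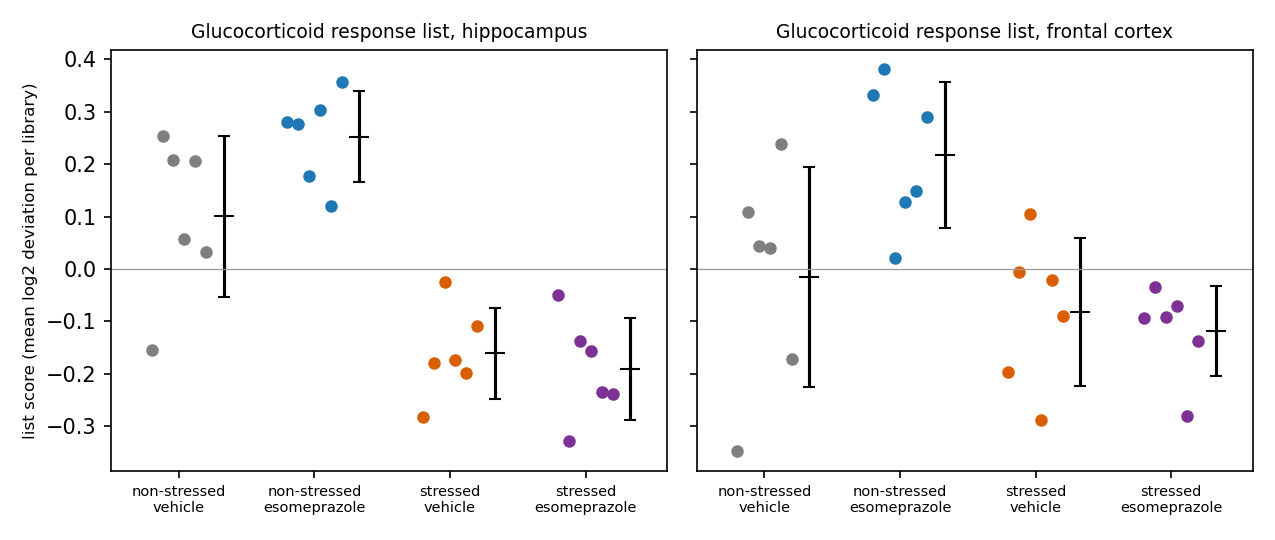
Score of the glucocorticoid response list per library (mean log2 deviation of the members), with 1 point per library and bars for the mean ± SD of 6 libraries per group, in both tissues. In hippocampus the group means were 0.10 and 0.25 without stress (vehicle and esomeprazole) and -0.16 and -0.19 with stress.

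**Figure D3:**
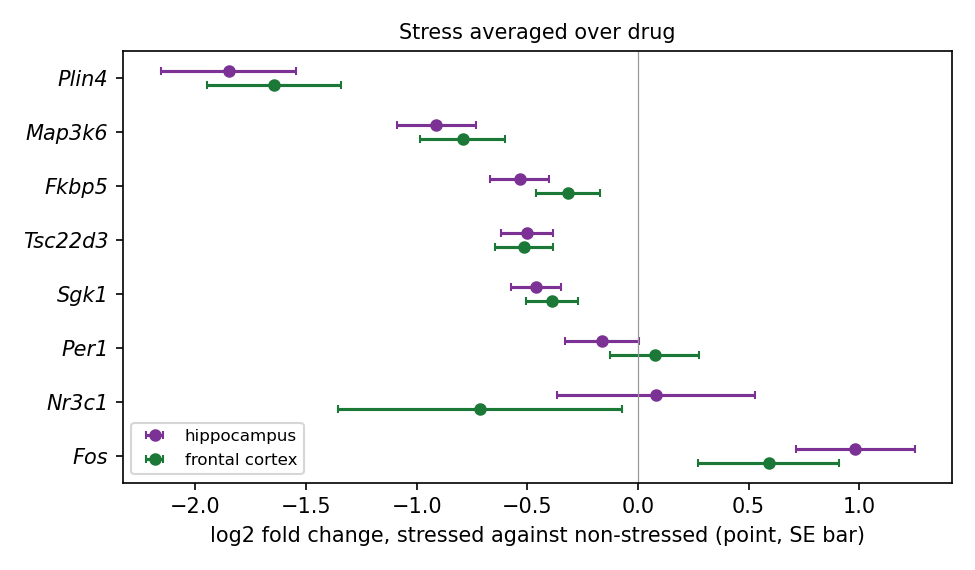
Log2 fold change after stress, averaged over drug, of 8 genes in both tissues, with bars for ± 1 SE (12 against 12 libraries). Plin4 lies at -1.85 in hippocampus and -1.64 in frontal cortex, and of the values drawn only Plin4 in hippocampus passed the limma test over all genes.

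Cell type markers also moved with stress in hippocampus. Markers of CA1 pyramidal neurons fell, with 8 of 9 lower and a median of -0.56 (camera adjusted p = 2.34e-07, and adjusted p = 0.0119 with an estimated correlation). Of these, 5 were called when adjusted over the list alone and 0 over all genes, and Nov and Dcn, which encode secreted matrix proteins, were at -0.56 ± 0.16 and -0.73 ± 0.26. Striatal markers rose, 15 of 15, by a median of 1.42 (camera adjusted p = 5.13e-20, but adjusted p = 0.0658 with an estimated correlation). Drd2 and Drd1 were at 1.99 ± 0.56 and 1.63 ± 0.49. Without the 5 libraries of high striatal markers, all from stressed mice, the median was -0.02 (adjusted p = 0.697). Here and below, the 5 were picked by the score of this same list. For striatal markers the loss of the rise therefore follows from that choice. Markers of dentate granule neurons fell, 14 of 14, with a median of -0.43 (adjusted p = 1.52e-06, and adjusted p = 0.216 with an estimated correlation), against -0.18 (adjusted p = 0.0600) without those 5 libraries. The transcription factor gene Prox1 was at -0.83 ± 0.31 and the cytokine gene Il16 at -0.96 ± 0.36, though Il16 was at 0.05 with 2 surrogate variables and the striatal score. Hypothalamic markers rose by a median of 1.17 over 8 members (adjusted p = 4.43e-05, and adjusted p = 0.266 with an estimated correlation). The rise was uneven between libraries. Their score ran from -1.19 to 3.61 in stressed vehicle mice (SD 1.84) and from -0.705 to 3.44 in stressed esomeprazole mice (SD 1.88). Genes of cholesterol synthesis rose by a median of 0.09, 19 of 25 being higher (adjusted p = 0.000762, and adjusted p = 0.12 with an estimated correlation). Cyp51 was at 0.19 ± 0.06.

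Over all 15062 hippocampal genes tested, limma called 2 genes lower and 0 higher (889 at an unadjusted p under 0.05). The test fixed at the outset, edgeR, called 7: Plin4, Lao1 and Lyve1 lower, and Sh3rf2, Casq2, Lhx8 and Cd4 higher. DESeq2 called 127. With the striatal score as a covariate, chosen after seeing the data, no gene was called (Plin4 was at -1.90 with the SE widened from 0.31 to 0.38 and adjusted p = 0.575, in a range from 3.75e-08 to 0.99999 over the alternatives). The CA1 median shrank to -0.21 with it and to -0.18 without the 5 libraries (adjusted p = 0.00274), and with the no-feature share as a further covariate the CA1 call was lost (adjusted p = 0.161).

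In vehicle mice alone (6 stressed against 6), glucocorticoid response genes fell in hippocampus, with 32 of 40 lower and a median of -0.26 (camera adjusted p = 2.04e-11, and adjusted p = 0.00309 with an estimated correlation). All 6 stressed libraries had a list score below the non-stressed mean, a difference of -0.26 that did not pass over the lists (exact permutation p = 0.0065, adjusted p = 0.26). Plin4 was at -1.75 ± 0.43 (SE), Map3k6 at -0.83 ± 0.25, Fkbp5 at -0.44 ± 0.19, Sgk1 at -0.42 ± 0.16, Tsc22d3 at -0.41 ± 0.17 and the glycosyltransferase gene Galnt15 at -0.53 ± 0.21. When adjusted over the list alone 1 member was called, and over all genes none. Lyve1 was at -1.29 ± 0.32 and Fos at 0.95 ± 0.38. CA1 markers fell, with a median of -0.38, 8 of 9 being lower (adjusted p = 0.000636, and adjusted p = 0.118 with an estimated correlation). Their score was -0.64 in stressed vehicle library 2. The other 5 stressed libraries lay from -0.10 to 0.36, against a non-stressed mean of 0.30. Striatal markers rose by a median of 0.57 and cholesterol synthesis genes by 0.07 (adjusted p = 0.003 for each), with adjusted p = 0.821 and adjusted p = 0.167 with an estimated correlation. The striatal rise was carried by 1 library, stressed vehicle library 2 with a score of 1.99, while the other 5 lay from -1.03 to -0.30 against a non-stressed mean of -0.74; without the libraries of high striatal markers the median was 0.08 (adjusted p = 0.547). By limma 0 genes were called (82 at an unadjusted p under 0.05), by edgeR 0 and by DESeq2 1.

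In esomeprazole mice (6 stressed against 6), 34 of 40 glucocorticoid response genes were lower in hippocampus after stress and the list fell, with a median of -0.40 (camera adjusted p = 7.14e-12, and adjusted p = 0.00286 with an estimated correlation). The score differed by -0.44, with 6 of 6 stressed libraries below the non-stressed mean (exact permutation p = 0.0022, the smallest that 924 regroupings allow, adjusted p = 0.087). Plin4 was at -1.95 ± 0.43 (SE), Map3k6 at -0.99 ± 0.25, Tsc22d3 at -0.60 ± 0.17 and Fkbp5 at -0.63 ± 0.19. In all 7 members were called when adjusted over the list alone against 0 over all genes. Striatal markers rose, 15 of 15, by a median of 2.21 (adjusted p = 4.49e-27, and adjusted p = 0.0199 with an estimated correlation). Drd2 was at 3.19 ± 0.79 and Drd1 at 2.64 ± 0.69. The rise was carried by the 4 libraries with high striatal markers. Without them, with 2 stressed libraries left, the median was -0.13 (adjusted p = 0.999), which the choice by this score implies. Over the list alone 14 striatal markers were called and over all genes 0. CA1 markers fell, 7 of 9 being lower, with a median of -0.74 (adjusted p = 1.16e-06, and adjusted p = 0.0199 with an estimated correlation). The CA1 score was -0.22, -1.40, -0.91 and -0.66 in those 4 libraries and 0.03 and 0.14 in the other 2, and without the 4 the median was -0.11 (adjusted p = 0.437). Dentate granule markers fell, 13 of 14 being lower, with a median of -0.85 (adjusted p = 3.92e-09, and adjusted p = 0.103 with an estimated correlation), against -0.50 (adjusted p = 0.240) without the 4. Over all markers of hippocampal neurons the score differed by -0.82 between the 4 and the other 2. Prox1 was at -1.39 ± 0.44. Genes of NF-kB and cytokine signalling fell, with a median of -0.15 (adjusted p = 0.0452, and adjusted p = 0.261 with an estimated correlation), among them the iron-binding lipocalin gene Lcn2 at -3.04 ± 1.03 and the prostaglandin synthase gene Ptgs2 at -1.22 ± 0.46. Ptgs2 was at 0.01 with 2 surrogate variables and the striatal score. Lao1 was at -2.01 ± 0.38 (adjusted p = 0.393) and Fos at 1.02 ± 0.38. By limma 0 genes were called (861 at an unadjusted p under 0.05), by edgeR 0 and by DESeq2 68, and with 2 surrogate variables limma called 996.

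In frontal cortex, over both drug arms (12 stressed against 12), glucocorticoid response genes fell after stress, with 28 of 40 lower and a median of -0.13 (camera adjusted p = 1.12e-06, and adjusted p = 0.0414 with an estimated correlation). The score differed by -0.20, with 11 of 12 stressed libraries below the non-stressed mean, and did not pass over the lists (permutation p = 0.0078, adjusted p = 0.149). Plin4 was at -1.64 ± 0.30 (SE, limma adjusted p = 0.200), with 417 ± 249 and 529.6 ± 238 normalised reads without stress (vehicle and esomeprazole, n = 6 each) and 122 ± 39.4 and 147 ± 52.9 with it. Galnt15 was at -0.72 ± 0.15, Map3k6 at -0.79 ± 0.19, the hypoxia-inducible factor gene Hif3a at -1.03 ± 0.26, Tsc22d3 at -0.52 ± 0.13, Sgk1 at -0.39 ± 0.12 and Fkbp5 at -0.32 ± 0.15. When adjusted over the list alone 8 members were called, and over all genes none. Genes of the circadian clock fell, with 18 of 24 lower and a median of -0.22 (adjusted p = 0.000385, and adjusted p = 0.0414 with an estimated correlation). Of these, 2 were called when adjusted over the list alone and 0 over all genes, and the clock repressor gene Ciart was at -0.70 ± 0.16 and Per2 at -0.49 ± 0.20.

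Markers of meningeal fibroblasts rose in frontal cortex after stress, with 17 of 20 higher and a median of 0.55 (camera adjusted p = 6.94e-11, and adjusted p = 0.102 with an estimated correlation). The collagen gene Col3a1 was at 0.72 ± 0.20, the retinoic acid synthesis gene Aldh1a2 at 0.86 ± 0.24 and the connexin gene Gjb2 at 0.73 ± 0.16. Kdr, a receptor for vascular endothelial growth factor, was at 0.59 ± 0.11 and Ly6g6f at 1.28 ± 0.25 (limma adjusted p = 0.200 for both). Choroid plexus markers rose by a median of 0.57 over 10 members (adjusted p = 1.14e-05, and adjusted p = 0.0627 with an estimated correlation). Olfactory bulb markers, low in 4 of the 6 non-stressed vehicle libraries, rose by a median of 1.32 over 15 members (adjusted p = 0.000103, and adjusted p = 0.318 with an estimated correlation). That group also had the lowest mean scores of meningeal fibroblast (-0.39) and choroid plexus (-0.58) markers. By limma 0 genes were called of 15040 tested (570 at an unadjusted p under 0.05). By edgeR, the test fixed at the outset, 1 was, Plin4 at -1.81 (adjusted p = 0.0349), and by DESeq2 10. With the no-feature share as a covariate, chosen after seeing the data, limma called 25 genes, and with 2 surrogate variables 13.

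In vehicle mice alone (6 stressed against 6), glucocorticoid response genes fell in frontal cortex, with a median of -0.12, with 25 of 40 lower (camera adjusted p = 0.0157), a call that was lost with an estimated correlation (adjusted p = 0.19). The score difference was -0.07, with 4 of 6 stressed libraries below the non-stressed mean (exact permutation p = 0.519). Plin4 was at -1.56 ± 0.43 (SE), Galnt15 at -0.68 ± 0.21, Sgk1 at -0.47 ± 0.17 and Map3k6 at -0.76 ± 0.27. Limma called 0 members, over the list alone or over all genes. Circadian genes fell, 20 of 24 being lower, with a median of -0.33 (adjusted p = 0.00107, and adjusted p = 0.0966 with an estimated correlation). Ciart was at -0.81 ± 0.22. Meningeal fibroblast markers rose, 19 of 20 being higher, by a median of 0.76 (adjusted p = 3.02e-09, and adjusted p = 0.19 with an estimated correlation). Col3a1 was at 0.86 ± 0.28 and Aldh1a2 at 1.09 ± 0.35. Olfactory bulb markers rose, 15 of 15, by a median of 2.72 (adjusted p = 5.37e-09, and adjusted p = 0.19 with an estimated correlation). In 4 of the 6 non-stressed libraries their score lay from -3.11 to -2.68, while libraries 3 and 5 lay at 0.60 and 1.28. Stressed library 4 lay at -2.12 and the others from 0.86 to 1.51. Eomes was at 4.69 ± 1.64 and the cadherin gene Cdhr1 at 3.52 ± 1.40, though Cdhr1 was at -0.02 with 2 surrogate variables and the bulb score. Eomes had 648 ± 1062 normalised reads (SD, n = 6) without stress and 1986 ± 1080 with it. Ly6g6f was at 1.74 ± 0.35 (limma adjusted p = 0.755). By limma 0 genes were called (973 at an unadjusted p under 0.05), by edgeR 0 and by DESeq2 1. With the no-feature share as a covariate limma called 5 genes, and the glucocorticoid list was not called (adjusted p = 0.105).

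In esomeprazole mice (6 stressed against 6), glucocorticoid response genes fell in frontal cortex, 31 of 40 being lower, with a median of -0.22 (camera adjusted p = 1.96e-13, and adjusted p = 0.0011 with an estimated correlation). The score differed by -0.34, with 6 of 6 stressed libraries below the non-stressed mean (exact permutation p = 0.0022, adjusted p = 0.087). Plin4 was at -1.73 ± 0.43 (SE), Galnt15 at -0.76 ± 0.21, Hif3a at -1.33 ± 0.36, Map3k6 at -0.82 ± 0.27 and Tsc22d3 at -0.54 ± 0.19. In all 3 members were called when adjusted over the list alone against 0 over all genes. Immediate early genes rose, 30 of 38 being higher, by a median of 0.12 (adjusted p = 0.00212, and adjusted p = 0.568 with an estimated correlation). The transcription factor gene Egr1 was at 0.67 ± 0.28. Circadian genes fell, with a median of -0.12 (adjusted p = 0.0142, and adjusted p = 0.271 with an estimated correlation). Meningeal fibroblast markers rose by 0.34 (adjusted p = 8.7e-07, and adjusted p = 0.394 with an estimated correlation). Kdr was at 0.69 ± 0.16. By limma 0 genes were called (71 at an unadjusted p under 0.05), by edgeR 0 and by DESeq2 1, and with 2 surrogate variables limma called 4.

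What esomeprazole did without stress was asked in 6 treated against 6 vehicle mice per tissue; the vehicle libraries here are also the reference of the stress comparison in vehicle mice. In hippocampus glucocorticoid response genes rose, 33 of 40 being higher, by a median of 0.14 (camera adjusted p = 0.000728, and adjusted p = 0.237 with an estimated correlation). Galnt15 was at 0.34 ± 0.21 and Hif3a at 0.62 ± 0.46. Choroid plexus markers fell, 15 of 15, with a median of -1.23 (adjusted p = 9.26e-08, and adjusted p = 0.681 with an estimated correlation). They varied widely between libraries of a group. Their score ran from -1.64 to 2.06 with vehicle (SD 1.26) and from -2.08 to 2.87 with esomeprazole (SD 2.15). Ttr, which encodes the thyroxine carrier transthyretin, was at -2.45 ± 1.62. Markers of mural cells, which line small vessels, fell, with a median of -0.20 (adjusted p = 0.00204, and adjusted p = 0.237 with an estimated correlation). The pericyte gene Higd1b was at -0.36 ± 0.15. Endothelial markers fell, with a median of -0.08 (adjusted p = 0.00426, and adjusted p = 0.423 with an estimated correlation). Kdr was at -0.37 ± 0.17. No gene was called by limma (0, with 35 at an unadjusted p under 0.05), edgeR (0) or DESeq2 (0).

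In stressed mice (6 esomeprazole against 6 vehicle), striatal markers rose in hippocampus, 15 of 15, by a median of 1.78 (camera adjusted p = 5.05e-34, and adjusted p = 0.021 with an estimated correlation), with 13 called when adjusted over the list alone and 0 over all genes. Drd2 was at 2.33 ± 0.79 and the striatal signalling gene Rgs9 at 1.78 ± 0.58, and Drd2 had 243 ± 339 normalised reads (SD, n = 6) with vehicle and 1083 ± 875 with esomeprazole. In the esomeprazole group 4 of the 6 libraries carried the rise, with scores from 2.06 to 3.31, while the others lay at -0.71 and -0.68, below the vehicle mean of -0.22, in which library 2 lay at 1.99. Without these 5 libraries of high striatal markers the median was -0.08 (adjusted p = 0.978). Dentate granule markers fell, 13 of 14 being lower, with a median of -0.73 (adjusted p = 5.73e-09, and adjusted p = 0.0853 with an estimated correlation), against -0.45 (adjusted p = 0.452) without the 5. Prox1 was at -1.05 ± 0.44. Heat shock genes fell, 29 of 30 being lower, with a median of -0.18 (adjusted p = 4.82e-06, and adjusted p = 0.0853 with an estimated correlation). Their score ran from -0.12 to 0.53 with vehicle (SD 0.24) and from -0.38 to 0.15 with esomeprazole (SD 0.19). The glucocorticoid list did not pass (median 0.00, 22 of 40 higher, adjusted p = 0.933). No gene was called by limma (0, with 221 at an unadjusted p under 0.05), edgeR (0) or DESeq2 (0).

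Averaged over stress (12 against 12), the effect of esomeprazole on Atp4a, Cyp1b1 and Ddah1 did not pass in hippocampus. Atp4a, the gastric proton pump subunit that the drug blocks, was at 0.05 ± 0.22, Cyp1b1, a target of the aryl hydrocarbon receptor, at 0.03 ± 0.24 and Ddah1, which degrades the nitric oxide synthase inhibitor ADMA, at -0.05 ± 0.10. The lists of proton pumps (adjusted p = 0.232), xenobiotic receptor targets (0.0937) and nitric oxide and ADMA genes (0.0762) were not called by camera. Striatal markers rose by a median of 0.94 (adjusted p = 1.27e-21, and adjusted p = 0.0922 with an estimated correlation), and without the 5 libraries of high striatal markers the median was -0.01 (adjusted p = 0.666). Choroid plexus markers fell, with a median of -0.78 (adjusted p = 1.9e-06, and adjusted p = 0.286 with an estimated correlation). Their score again varied widely, also in stressed mice, from -1.97 to 2.28 with vehicle and from -1.79 to 2.40 with esomeprazole. The smallest p among higher genes included those of Mir1943 at 1.26 ± 0.29 and of Snora68, a small nucleolar RNA, at 0.95 ± 0.24. By limma 0 genes were called (109 at an unadjusted p under 0.05), by edgeR 0 and by DESeq2 0. On the deposited scale the median of all genes was higher with esomeprazole by 0.18 (log2) in hippocampus and differed by -0.02 in frontal cortex, and all changes here are relative to a joint scaling that removes this shift. Ddah1 was at 0.14 in hippocampus on the deposited scale, and Cyp1b1 at -0.07 with edgeR and -0.08 with DESeq2, each with the opposite sign. Atp4a was at -0.08 with the striatal score as a covariate, -0.06 with 2 surrogate variables as well, and -0.04 without the libraries of low no-feature share.

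In frontal cortex without stress (6 esomeprazole against 6 vehicle), olfactory bulb markers rose, 15 of 15, by a median of 2.73 (camera adjusted p = 1.53e-11, and adjusted p = 0.264 with an estimated correlation). Eomes was at 4.66 ± 1.64 and Cdhr1 at 3.68 ± 1.40. The vehicle group holds 4 of the 7 libraries with low bulb markers. Markers of excitatory cortical neurons fell, 11 of 11, with a median of -0.79 (adjusted p = 3.76e-06, and adjusted p = 0.264 with an estimated correlation). Their mean score was 0.52 and -0.17 without stress (vehicle and esomeprazole) and -0.06 and -0.29 with it. A drug effect in this comparison is not told apart from the difference in bulb markers. The synaptic vesicle gene Sv2b was at -0.79 ± 0.33 and the transcription factor gene Tbr1 at -0.83 ± 0.38. Cholesterol synthesis genes fell, 24 of 25 being lower, with a median of -0.22 (adjusted p = 0.00145, and adjusted p = 0.264 with an estimated correlation). Cyp51 was at -0.34 ± 0.16. Glucocorticoid response genes rose, 31 of 40 being higher, by a median of 0.13 (adjusted p = 0.0134, and adjusted p = 0.264 with an estimated correlation). Galnt15 was at 0.53 ± 0.21. No gene was called by limma (0, with 668 at an unadjusted p under 0.05), edgeR (0) or DESeq2 (0).

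In stressed mice (6 against 6), immediate early genes fell with esomeprazole in frontal cortex, 28 of 38 being lower, with a median of -0.13 (camera adjusted p = 0.0185, and adjusted p = 0.855 with an estimated correlation). Among them the nuclear receptor genes Nr4a3 and Nr4a2 were at -0.64 ± 0.38 and -0.48 ± 0.39, and Fos at -0.30 ± 0.45. Striatal markers rose by a median of 0.20 (adjusted p = 0.0149, and adjusted p = 0.855 with an estimated correlation). Their score was 0.95 and 0.94 in esomeprazole libraries 4 and 1, which carried the rise, while the other 4 had a mean of -0.22, below the vehicle mean of -0.07. Limma called 0 genes (28 at an unadjusted p under 0.05), edgeR 0 and DESeq2 0. Averaged over stress (12 against 12), olfactory bulb markers rose by a median of 1.30 (adjusted p = 4.83e-07, and adjusted p = 0.362 with an estimated correlation). Their mean score was -1.64 in non-stressed vehicle mice, against 0.59, 0.58 and 0.46 in the other groups. The same group had the highest mean scores of the excitatory neuron and cholesterol synthesis lists (0.52 and 0.14). Eomes was at 2.34 ± 1.16. Markers of excitatory cortical neurons fell, with a median of -0.41 (adjusted p = 8.71e-06, and adjusted p = 0.362 with an estimated correlation). Cholesterol synthesis genes fell, with a median of -0.12, 24 of 25 being lower (adjusted p = 0.00295, and adjusted p = 0.362 with an estimated correlation). Galnt15 was at 0.49 ± 0.15, Cyp1b1 at 0.51 ± 0.43, Atp4a at -0.26 ± 0.24 and Ddah1 at -0.01 ± 0.09. The lists of proton pumps (adjusted p = 0.0549), xenobiotic receptor targets (0.929) and nitric oxide and ADMA genes (0.720) were not called. Limma called 0 genes for the averaged effect (164 at an unadjusted p under 0.05), edgeR 0 and DESeq2 0.

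Whether esomeprazole altered the response to stress was tested as the interaction in each tissue, the stress effect in esomeprazole mice minus that in vehicle mice. The glucocorticoid list did not pass in hippocampus (median -0.14, 29 of 40 lower, camera adjusted p = 0.0589) or in frontal cortex (median -0.13, 33 of 40 lower, adjusted p = 0.0770). In hippocampus striatal markers rose by a median of 1.66 (adjusted p = 1.11e-20, and adjusted p = 0.175 with an estimated correlation), against -0.15 (adjusted p = 0.978) without the 5 libraries of high striatal markers. Drd2 was at 2.39 ± 1.12, and dentate granule markers fell, with a median of -0.90 (adjusted p = 4.5e-07, and adjusted p = 0.307 with an estimated correlation), against -0.47 (adjusted p = 0.666) without the 5. Prox1 was at -1.11 ± 0.62. In frontal cortex olfactory bulb markers fell, 15 of 15, with a median of -2.80 (adjusted p = 1.64e-11, and adjusted p = 0.361 with an estimated correlation). The non-stressed vehicle group stood apart in them, with a mean score of -1.64 against 0.59, 0.58 and 0.46 in the other groups. Eomes was at -4.64 ± 2.32 and Igfbpl1 at -3.91 ± 1.94. No gene passed in limma (0 in both tissues, with 57 at an unadjusted p under 0.05 in hippocampus and 109 in frontal cortex), and edgeR and DESeq2 called 0 in both.

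The tissues themselves were compared in non-stressed vehicle mice, 6 libraries of each. Of 14844 genes tested in both, limma called 679 higher and 682 lower in hippocampus, 1361 in all (2611 at an unadjusted p under 0.05), while edgeR called 1395 and DESeq2 1620. Higher in hippocampus were Ttr by 8.76 ± 1.25 (log2, SE), C1ql2, a synaptic protein gene of mossy fibres, by 7.28 ± 0.70, Fibcd1 by 3.99 ± 0.59, and Prox1 by 3.44 ± 0.39. Lower in hippocampus were Dkkl1 at -4.02 ± 0.64, Rasgef1c at -3.91 ± 0.55, and the upper-layer cortical genes Lamp5 and Cux2 at -2.55 ± 0.38 and -2.01 ± 0.26. Nr3c2, the mineralocorticoid receptor gene, was higher in hippocampus by 2.11 ± 0.37, Fkbp5 by 1.13 ± 0.20 and Sgk1 by 0.64 ± 0.16, and Fos was lower at -1.48 ± 0.43 (limma adjusted p = 0.018). Of 34 stress hormone and monoamine genes, 11 were called over all genes, 4 of them higher, and 13 when adjusted over the list alone, while the list as a whole did not pass (adjusted p = 0.528) with a median of 0.02 and a mean of -0.20.

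By cell type, markers of dentate granule neurons were higher in hippocampus by a median of 1.39 (camera adjusted p = 2.3e-09), of CA1 neurons by 0.40 (0.00577) and of CA3 and CA2 neurons by 0.82 (0.0151). Choroid plexus markers were higher by a median of 4.04 (adjusted p = 9.14e-13), ependymal markers by 1.24 (0.000351) and oligodendrocyte markers by 1.08 (1.86e-11). The myelin gene Mobp was at 1.20 ± 0.18. Markers of upper-layer cortical neurons were lower, 11 of 12, with a median of -1.52 (adjusted p = 2.18e-07). When adjusted over the list alone the calls were 7 of 12 dentate, 5 of 9 CA1, 8 of 12 CA3 and CA2, 8 of 10 choroid plexus, 5 of 7 ependymal, 13 of 20 oligodendrocyte and 10 of 12 upper-layer genes, against 6, 5, 7, 7, 5, 10 and 9 over all genes. With the no-feature share as a covariate, chosen after seeing the data, 3368 genes were called, and without the libraries of low no-feature share 2959.

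The difference of the stress effect between the tissues, hippocampus minus frontal cortex, was called for 0 genes by limma (566 at an unadjusted p under 0.05), 0 by edgeR and 15 by DESeq2. Striatal markers, high in 5 libraries of stressed mice in hippocampus, were higher in this difference by a median of 1.19 (camera adjusted p = 5.41e-13, and adjusted p = 0.0963 with an estimated correlation). Drd1 was at 1.62 ± 0.57. The glucocorticoid list did not pass (median -0.17, 24 of 40 lower, adjusted p = 0.0589), and Fkbp5 was at -0.22 ± 0.20. The difference of the esomeprazole effect was called for 0 genes by limma (126 at an unadjusted p under 0.05), edgeR (0) or DESeq2 (0). Striatal markers were higher in it by a median of 0.63 (adjusted p = 8.1e-05, and adjusted p = 0.495 with an estimated correlation). Drd1 was at 0.97 ± 0.57, and olfactory bulb markers lower, with a median of -0.52 (adjusted p = 0.000516, and adjusted p = 0.495 with an estimated correlation). Cdhr1 was at -2.04 ± 1.03.

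Of 680 list tests, 200 passed with the preset correlation and 17 with an estimated one. Those 17 were the glucocorticoid list in hippocampus (stress in vehicle mice, in esomeprazole mice and averaged) and in frontal cortex (stress in esomeprazole mice and averaged), the circadian list in frontal cortex (stress averaged), CA1 markers in hippocampus (stress in esomeprazole mice and averaged), striatal markers in hippocampus (stress in esomeprazole mice, and esomeprazole in stressed mice), and the 7 cell type lists of the tissue comparison.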

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

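All explanations weighed here, with their tests, were chosen after the results they concern had been seen.

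Glucocorticoid response genes were lower after stress in hippocampus, with a list score difference of -0.35. Taking the no-feature share of reads out within groups left -0.35055 (SE 0.0459, exact permutation p = 9.4e-06), and taking the striatal marker score out left -0.36738 (SE 0.0558, exact permutation p = 7e-06), which argues against library quality along that share and against striatal tissue as the whole cause. Taking out the score of clock output genes minus that of their activators left -0.34 (SE 0.0467, exact permutation p = 9.4e-06), but a time of day that differed only between the groups would leave no trend within them. Another time of day at collection therefore cannot be told apart: that score differed by -0.29079 (exact permutation p = 0.175), and in frontal cortex circadian genes fell after stress (adjusted p = 0.0414 with an estimated correlation, Ciart at -0.70 ± 0.16). A lower hormone signal 12 hours after the last injection, which stress may have caused, stays open as a hypothesis.

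Striatal markers were high in 4 of the 6 hippocampal libraries of stressed esomeprazole mice and in 1 library of a stressed vehicle mouse. If striatal tissue lay in the dissected piece, markers of hippocampal neurons should be lower in these 5 libraries than in the other 7 of their groups. Their score (36 genes, none in the striatal list) differed by -0.79453 (SE 0.349, exact permutation p = 0.10, smallest possible 0.011), which leaves striatal tissue open. Drd2, an abundant striatal transcript, had 1083 ± 875 normalised reads in the group of stressed esomeprazole mice. For the 4 libraries of esomeprazole mice, esomeprazole after stress turning the markers on in some mice cannot be told apart from striatal tissue. That 2 libraries of the group lay below the highest library of another group (1.99) only restates the pattern. The stressed vehicle mouse was given no esomeprazole, so its library is not covered by that explanation.

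On the deposited scale the median of all genes was higher with esomeprazole in hippocampus by 0.18 (log2). Size factors computed within each drug set gave the deposited factors to within 0.0157%, and their ratio to joint factors gives a shift of 0.20 between the drug sets, so separate scaling accounts for the pattern. Whether RNA per cell also differed with esomeprazole cannot be told apart in these libraries: joint scaling gives -0.006673, but it centres the median by construction, and no spike-in was measured.

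In 16 of 120 combinations of a group and a measure the highest or lowest library stood apart from the other 5 (Dixon's ratio above 0.625). For independent values with a normal spread chance gives about 1 in 20. The measures overlap (Drd2 is in the striatal score) and normalised reads were not put on a log scale. That rate therefore need not hold here. In hippocampus, Drd2 had 184.86 normalised reads in non-stressed vehicle library 3 and 897.41 in stressed vehicle library 2, whose striatal score was 1.9917 and bulb score 0.71747. Fos had 1277 normalised reads in stressed vehicle library 3 and 178.81 in non-stressed esomeprazole library 4, whose no-feature share was 6.1161% (95% Wilson interval 6.11 to 6.12). Fkbp5 had 4090.4 in non-stressed esomeprazole library 1, and Sgk1 4042.8 in stressed esomeprazole library 1. In frontal cortex, non-stressed vehicle library 4 had a no-feature share of 4.4975% (4.49 to 4.50) and 409.99 normalised reads of Map3k6. Non-stressed esomeprazole library 2 had 718.82 reads of Drd2 and a striatal score of 1.6016. Bulb scores were -2.1693 in non-stressed esomeprazole library 3, -2.1189 in stressed vehicle library 4 and -2.5703 in stressed esomeprazole library 5. Each of these stood apart only from the other 5 of its group. Non-stressed vehicle libraries 1, 2, 4 and 6 lay lower still, from -3.11 to -2.68. Whether the libraries of higher bulb score held olfactory bulb tissue was not tested.

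Of 160 list tests of interactions and tissue differences, 34 passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.0963), and limma called 0 genes.

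The real grouping and random splits of the same libraries into groups of the same sizes, 100 in all per comparison, were compared by the number of genes called. For the hippocampus against the frontal cortex (1361 genes, highest other split 263) only 1 of the 100, the real grouping, was as large. This argues against chance. For stress averaged in hippocampus (2 genes) 2 of 100 were as large, the real grouping included, a share under 1 in 20, but the highest other split gave 7701, so a count of 2 is small beside what the structure of the samples can give. Where 0 genes were called, 100 of 100 splits gave as many by construction, which says nothing about chance. In hippocampus the highest other split gave 0 genes for stress in vehicle mice, 1 in esomeprazole mice, 0 for esomeprazole without stress, 453 with stress, 1 for the interaction and 6929 for esomeprazole averaged. In frontal cortex it gave 0 for stress in vehicle mice, 7771 in esomeprazole mice, 9439 averaged, 0 for esomeprazole without stress, 0 with stress, 2386 averaged and 8596 for the interaction. It gave 9163 for the tissue difference of the stress effect and 9426 for that of the esomeprazole effect. Splits that call this many genes, up to 9439, point to a structure of the samples that the groups do not follow. The first principal component (67.4% of the variance in hippocampus, 71.4% in frontal cortex) had every library with a no-feature share under 12% on one side of all others. Next, 40 splits were fitted with 2 surrogate variables, the real grouping counted among them. For stress in hippocampus it called 996 genes in esomeprazole mice and 536 averaged (highest other 0, 1 of 40 as large for each). With the striatal score added to the surrogate variables 0 genes were called for both. Of the 15 striatal markers 13 were among the 996 and 6 among the 536, all higher. Of the 40 glucocorticoid response genes 14 were called in each fit, all lower. In frontal cortex 1 of 40 was as large for stress in esomeprazole mice (4 genes, highest other 1). Averaged, 2 of 40 were (13, highest other 13), which leaves chance open. A share of 1 of 40 is the smallest that 40 splits allow and was not adjusted over the comparisons. It argues against chance without excluding it.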

How the results depend on the processing

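Settings not listed as planned in the methods, such as the covariates and the subsets, were chosen after seeing the results. So was limma as the main test, while edgeR with TMM was the test fixed at the outset. Of the counts of called genes 29 moved by over 1.5 times under an alternative and 208 did not, but 197 of these were 0 in both fits, which says little of stability; of the values of named genes 1642 kept their direction and side of the threshold, 79 gained and 10 lost a call, and 21 turned direction, each uncalled in the main analysis. The glucocorticoid list stayed called in hippocampus for stress averaged under each alternative run (median -0.24 to -0.32). For the moves below the cause was not tested, except that fits on fewer libraries hold fewer samples.

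For stress averaged in hippocampus (2 genes), edgeR called 7 with TMM and 7 with median-of-ratios factors, DESeq2 127, the replicate block (which shares only a number) 1, Lyve1, with Plin4 (adjusted p = 0.121) and Lao1 (0.209) both lost, and 2 surrogate variables 536. The no-feature covariate gave 18, leaving out libraries of low no-feature share 12, and 0 remained with the neighbouring-tissue score, both covariates, surrogate variables with that score, and 1 marker class. There Plin4 stayed between -1.90 and -1.97 with adjusted p from 0.0571 to 0.99999. Where limma called 0 genes, DESeq2 called 1 for stress in vehicle mice in hippocampus, 68 in esomeprazole mice, 1 in either arm in frontal cortex, 10 averaged there, and 15 for the tissue difference of the stress effect. With 2 surrogate variables limma called 996 for stress in esomeprazole mice in hippocampus, 4 in frontal cortex and 13 averaged there; with the neighbouring-tissue score added, 0, 1 and 12. For stress averaged in frontal cortex edgeR called 1 with each factor method, the no-feature covariate gave 25 and both covariates 15, and for vehicle mice the no-feature covariate gave 5. The tissue comparison rose from 1361 to 3368 with the no-feature covariate and 2959 without libraries of low share. With an estimated correlation 17 list tests passed, not 200, and the glucocorticoid list in frontal cortex, vehicle mice, was lost (adjusted p = 0.19012), as with the no-feature covariate (0.10471).

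These uncalled genes turned direction (log2). Averaged esomeprazole in hippocampus: Cyp1b1 -0.077367 with edgeR median-of-ratios, -0.068764 with edgeR TMM, -0.077587 with DESeq2, -0.070599 with surrogate variables, -0.11494 with the no-feature covariate and -0.22273 without low-share libraries. Ddah1 there was 0.0025066 with surrogate variables, 0.13853 on the deposited scale and 0.078379 without low-share libraries, and Atp4a -0.082808 with the neighbouring-tissue score, -0.057341 with surrogate variables added and -0.036856 without low-share libraries. In frontal cortex, averaged, Ddah1 was 0.029044 with surrogate variables, 0.045028 with the neighbouring-tissue score, 0.039737 with both covariates, 0.033164 with surrogate variables and that score and 0.027032 in 1 marker class. With surrogate variables and that score, Ptgs2 was 0.0051865 (stress, esomeprazole mice) and Il16 0.05055 (stress averaged) in hippocampus, and Cdhr1 -0.01866 (stress, vehicle mice) in frontal cortex. Fos was 0.23281 without low-share libraries (esomeprazole, stressed mice, frontal cortex). Each library held at least 25.3 M gene reads; what depth limits was not compared with what the spread between libraries limits.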

Other observations

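The test of a correlation between tissues was chosen after the scores had been seen; the gene groups were fixed before.

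Interferon-response genes rose after stress in frontal cortex, with 31 of 33 higher and a median log2 fold change of 0.26 (camera adjusted p = 1.38e-08, and adjusted p = 0.158 with an estimated correlation, 12 against 12 libraries). Gbp2, a guanylate-binding protein gene, was at 0.52 ± 0.17 (SE) and Isg15, a ubiquitin-like modifier, at 0.51 ± 0.19. The list rose by a median of 0.37 in vehicle mice, 32 of 33 being higher (adjusted p = 4.45e-06, and adjusted p = 0.19 with an estimated correlation), and by 0.21 in esomeprazole mice, 27 of 33 being higher (adjusted p = 5.56e-07, and adjusted p = 0.393 with an estimated correlation). The score was higher by 0.29 on average, with 10 of 12 stressed libraries above the non-stressed mean (exact permutation p = 0.0504, adjusted p = 0.286). The non-stressed vehicle group, with 4 of 6 libraries low in olfactory bulb markers, also had the lowest mean scores of bulb (-1.64), meningeal fibroblast (-0.39) and choroid plexus (-0.58) markers and of the interferon list (-0.25). Mural cell markers rose by a median of 0.23 in the averaged comparison (adjusted p = 0.000274, and adjusted p = 0.0627 with an estimated correlation). Their score was higher by 0.21 on average, with 12 of 12 stressed libraries above the non-stressed mean (exact permutation p = 0.00174, adjusted p = 0.0695).

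Immediate early genes fell with esomeprazole averaged over stress in both tissues, with a median of -0.14 in hippocampus with 31 of 38 lower (camera adjusted p = 1.46e-05, and adjusted p = 0.286 with an estimated correlation) and of -0.16 in frontal cortex with 27 of 38 lower (adjusted p = 0.0105, and adjusted p = 0.547 with an estimated correlation). In hippocampus Fos was at -0.52 ± 0.27 and Arc, a synaptic plasticity gene, at -0.49 ± 0.31; in frontal cortex the phosphatase gene Dusp6 was at -0.26 ± 0.10, Nr4a3 at -0.61 ± 0.27 and Egr1 at -0.42 ± 0.20. The scores did not pass, with 10 of 12 esomeprazole libraries below the vehicle mean in each tissue (exact permutation p = 0.209 and 0.137). In hippocampus the vehicle mean rests on an uneven group. The immediate early score ran from -0.36 to 0.94 in stressed vehicle mice (SD 0.45) and from -0.08 to 0.12 in non-stressed ones. With esomeprazole it ran from -0.34 to 0.19 and from -0.19 to 0.49. Heat shock genes fell, with a median of -0.14 in hippocampus, 27 of 30 being lower (adjusted p = 1.9e-07, and adjusted p = 0.0922 with an estimated correlation), and of -0.12 in frontal cortex (adjusted p = 0.0105, and adjusted p = 0.362 with an estimated correlation). In hippocampus their score ran from -0.12 to 0.53 in stressed vehicle mice and from -0.04 to 0.15 in non-stressed ones. With esomeprazole it ran from -0.38 to 0.15 and from -0.06 to 0.02.

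If the tissues bearing the same mouse number come from 1 animal, a shared hormone level may move the glucocorticoid score in both. Over 24 mouse numbers the deviations from group means correlated with r = 0.66582 (permutation p = 0.00223, adjusted p = 0.0892 over 40 lists) and rho = 0.543 (p = 0.0113, adjusted p = 0.232), and r was 0.52 without the 2 numbers farthest from the median. The adjusted p does not pass, and the labels do not say that a number marks the same mouse, so this cannot be told apart from chance.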
